A study of Mus musculus with 6 samples.

How the data were processed

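Total RNA from aortas of aged C57BL/6 mice was sequenced in 6 samples, 3 WT and 3 Sirt2-KO, and groups and replicate numbers were taken from the sample titles. The authors deposited a table of FPKM values (fragments scaled by transcript length and library size, per the file headers), with 1 column for each sample. Bowtie 0.12.2 and the genome build mm9 are named in the submitters' processing notes with no role given, and the quantifier, annotation and filters are not given in the sources used here. The table has 14083 rows. Among its 8690 gene names, 5703 have 1 row and 2987 have several, up to 13, as a table of transcripts without identifiers would. No row has a variance over the 6 samples under 1.00003, so rows with less variance were left out before deposit. Such a cut on the FPKM scale falls mainly on low transcripts. Steady transcripts of high level can remain, and all 44 genes of a ribosomal protein list were tested. In 39 rows the name had turned into a calendar date, and these were left out because several symbols can give the same date. Of the names, 8521 match a current symbol in the GRCm38 annotation, and 8659 match a current or older one. That assembly differs from mm9 and was used here only for names, transcript lengths, chromosomes and which genes are neighbours. Depth per sample is unknown, so no counting interval is given.

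From these values, rows with the same gene name were summed, and the 8605 genes with a mean of at least 1 FPKM over the 6 samples were tested. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A pseudocount of 1 makes a log2 difference understate the change of low genes. Means are given in FPKM with the SD over 3 mice, and folds are ratios of those means. The 48 gene lists, the tests, the rule for naming genes and all alternatives except 2 were fixed before the data were examined, but not whether the list test allows for a trend in the spread. Lists with at least 3 tested members (43 of 48) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. A trend in the spread was used to match the gene test, a choice made when both outcomes had been seen: 20 lists were called with it and 19 without, where the endothelial list missed the threshold (adjusted p = 0.0627). The 5 lists with too few tested members hold T and NK cell, mesothelial, mitochondrially encoded, Y-linked and X-inactivation genes. With an estimated correlation 0 of 43 lists passed (smallest adjusted p = 0.760), and 0 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance in 1 direction, called 0 lists (smallest adjusted p = 0.106, 9 lists at an unadjusted p under 0.05), and its mixed test, for change in either direction, called 20.

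Genes named in the text are Sirt2, in each direction the 8 called genes with the largest difference and the 5 with the smallest p whose groups did not overlap (without clone-type names), the 3 members with the smallest p in the direction of each called list, up to 3 called members of other lists, and a set of genes of ageing, redox and vessel wall biology named in advance (Shc1, Cdkn1a, Cdkn2a, Eln, Col1a1, Col3a1, Acta2, Myh11 and Nnt). A gene that the rule names is not reported here. Fabp4, Lpl, Ucp1, Th and Myh6 are given besides for single aortas or for contrast and were chosen after their values were seen. No pair of samples shared identical values, and Pearson correlations of log2 values lay between 0.925 and 0.963 within groups and between 0.850 and 0.936 across them. The highest across groups, of WT replicate 2 with Sirt2-KO replicate 4, exceeded 2 of the 3 WT pairs (0.925 and 0.931). On the first principal component (49.7% of the variance) Sirt2-KO replicate 4 lay between the groups, at 5.70 against 34.8 and 41.5 in the other Sirt2-KO aortas and -14.0, -28.4 and -39.5 in WT. The limma steps were tested on simulated data: for Sirt2-KO against WT with 8605 genes and the spread of the real ones, 49 of 100 genes changed by 1 on the log2 scale and 80 of 100 changed by 2 were called, with 11 unchanged genes called. In a simulated list test with 1 list raised, that list and 1 other were called. Simulated genes varied independently, without the correlation between real genes, so these counts may understate false calls. Alternatives covered other pseudocounts, filters, scalings, spread models, sample weights, the replicate number as a block and each mouse left out. The fits with a minimum mean of 20 FPKM and with only the highest row of each gene were added after seeing the data. Figures were drawn with matplotlib 3.10.9.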

Results

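Gene expression was measured by RNA sequencing in aortas of aged C57BL/6 mice, 3 wild type (WT, replicates 2, 4 and 8) and 3 without Sirt2 (Sirt2-KO, replicates 4, 7 and 8), each sample from its own mouse. Sirt2 encodes a deacetylase that uses NAD and is known for removing acetyl groups from tubulin. The comparison asks how the transcriptome of the aged aorta differs when Sirt2 is missing. The table gave FPKM values in 14083 rows. It held 8690 distinct gene names once 39 rows with a date in place of a name were left out, and values of rows with the same name were added up. Depth is unknown, because the table holds no counts, and its column sums (367746 to 396901 FPKM) cover only the rows that were listed. The smallest variance of any row over the 6 samples was 1.00003, so transcripts that varied little in FPKM, mainly low ones, were missing and a gene's sum can be partial.

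Sirt2 itself was lower in every Sirt2-KO aorta, with 2.70 ± 0.560 FPKM against 36.6 ± 11.6 FPKM in WT (SD, n = 3 each). The log2(FPKM + 1) difference was -3.31 (SE 0.239, adjusted p = 0.00156). The 3 WT values were 26.5, 34.1 and 49.2 FPKM and the 3 Sirt2-KO values 2.56, 3.32 and 2.23 FPKM. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Of the 3 rows summed for Sirt2, the highest in WT was at 18.5, 18.8 and 41.5 FPKM there, at 1.89 FPKM in Sirt2-KO replicate 4 and listed at 0 in replicates 7 and 8. In another the groups overlapped, at 2.59, 9.69 and 6.42 FPKM in WT and 0.110, 3.05 and 2.01 FPKM in Sirt2-KO (exact two-sided permutation p = 0.2). Fasn, the fatty acid synthase, rose from 22.9 ± 13.4 to 809 ± 305 FPKM (35.4-fold, log2 difference 5.15, adjusted p = 0.00291). The desaturase Scd1 rose from 81.3 ± 47.8 to 1287 ± 382 FPKM (log2 difference 4.14, adjusted p = 0.0158).

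Among genes with more than a clone-type name, further large rises were in Thrsp, a regulator of lipogenesis (log2 difference 3.84), Cfd, the adipocyte protease adipsin (3.74), the pyruvate carboxylase gene Pcx (3.69, and 5.61 with only its highest row), the cytochrome P450 gene Cyp1a1 (3.66), Tmem45b (3.48) and the carbonic anhydrase gene Car3 (3.42). Their adjusted p lay between 0.0108 for Pcx and 0.0359 for Tmem45b. The smallest p among rises of such genes belonged to Plac9b (45.7 ± 4.68 to 306 ± 26.0 FPKM, adjusted p = 0.000321) and Plac9a (41.5 ± 4.40 to 279 ± 24.7 FPKM), near-identical neighbours whose reads can be split between them. Next were the mitochondrial citrate carrier Slc25a1 (54.2 ± 4.54 to 389 ± 55.5 FPKM), Retnla, a gene of alternatively activated macrophages and fat (4.61 ± 1.40 to 54.3 ± 3.46 FPKM), and the malic enzyme gene Me1 (33.2 ± 2.98 to 232 ± 40.7 FPKM).

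Among genes without clone-type names other than Sirt2, the largest falls on the log2(FPKM + 1) scale were in Ighg2c and Nnat. Ighg2c, an immunoglobulin heavy chain gene, varied widely among WT samples (50.9 ± 44.0 to 0.989 ± 0.799 FPKM, log2 difference -4.36, adjusted p = 0.0282). The imprinted gene Nnat fell from 20.1 ± 9.90 to 2.16 ± 1.46 FPKM. Sparcl1, a matricellular protein gene, fell from 981 ± 124 to 215 ± 19.9 FPKM (log2 difference -2.18, adjusted p = 0.00156). Nav2 (log2 difference -2.14), the mitochondrial transhydrogenase Nnt (-1.77), AI838599 (-1.70) and the netrin receptor gene Unc5c (-1.68) also fell. By the ratio of means Nav2 fell more than Nnat (43.4-fold against 9.28-fold), with Sirt2-KO values of at most 0.165 FPKM. Tor1aip2 (14.2 ± 0.336 to 3.94 ± 0.287 FPKM) and the integrin subunit gene Itgav (19.3 ± 1.69 to 7.03 ± 0.280 FPKM) were among the falls with the smallest p.

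In all, 250 of 8605 tested genes passed an adjusted p of 0.05 in limma, 197 higher and 53 lower in Sirt2-KO, and of these 165 rose and 31 fell at least 2-fold on the log2(FPKM + 1) scale. Unadjusted p under 0.05 was reached by 2132 genes, where 430 would be expected by chance on average. The 3 values of each group lay apart in 33.3% of tested genes, against an average of 10% by chance. Genes that vary together can move such counts far from their average, so these averages do not show how firm the excess is. With the aortas split 3 against 3 in ways that mix the genotypes, 50 to 877 genes reached an unadjusted p under 0.05. The count of 250 genes rested on several aortas. It was 71 without WT replicate 2, 148 without WT replicate 8, 28 without Sirt2-KO replicate 7 and 29 without Sirt2-KO replicate 8. Of the 58 named genes that passed, 14 did so whichever mouse was left out: Sirt2, Fasn, Acaca, Acly, Me1, Slc25a1, Plac9a, Plac9b, Retnla, Pi16, Sparcl1, Tor1aip2, Itgav and AI838599.

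**Figure D1:**
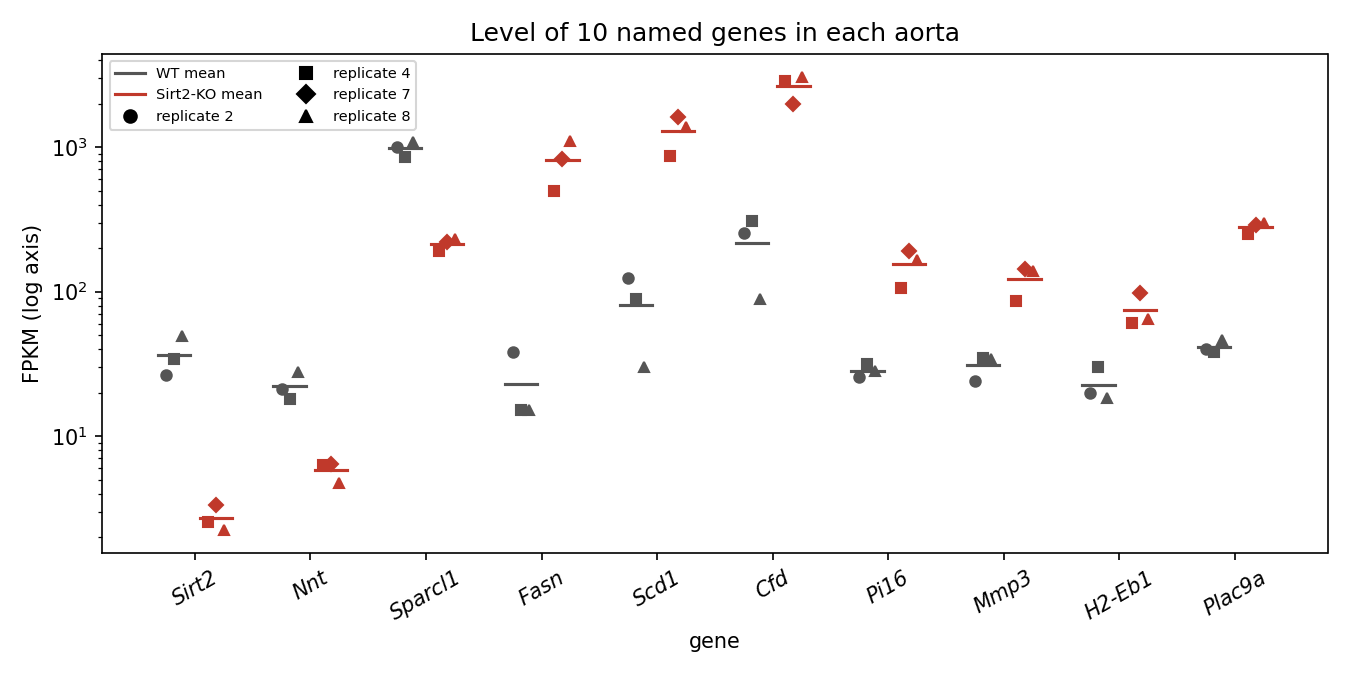
FPKM on a log axis (y) of 10 genes (x) in each aorta, grey for WT and red for Sirt2-KO, with a symbol for each replicate number and a line at each group's mean. Sirt2, Nnt and Sparcl1 lie lower in all 3 Sirt2-KO aortas than in all 3 WT aortas, and the other 7 genes lie higher, with Fasn at means of 22.9 and 809 FPKM.

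White adipocyte markers rose as a list: 9 of 21 tested members passed over all genes and 16 when adjusted over the list alone. The median log2 difference was 2.51 (camera adjusted p = 3.5e-12, and adjusted p = 0.760 with an estimated correlation). Besides Fasn, the ATP citrate lyase gene Acly went from 36.7 ± 2.07 to 303 ± 108 FPKM and the acetyl-CoA carboxylase gene Acaca from 11.6 ± 3.18 to 107 ± 37.8 FPKM. The log2 difference of Acaca ranged from 2.82 to 6.59 over the alternatives. Fabp4 differed by 0.60 (SE 0.497, adjusted p = 0.461) and Lpl by 1.08 (SE 0.686, adjusted p = 0.349), and neither passed. WT replicate 8 had the lowest Fabp4, 426 FPKM against 1552 and 1504 FPKM in the other WT aortas and 1251 to 1741 FPKM in Sirt2-KO. The adipocyte list also passed without that aorta. Of 12 brown adipocyte markers 0 passed by limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 (adjusted p = 0.544 for the list). Ucp1 stood at 475, 419 and 35.1 FPKM in WT and at 107, 101 and 245 FPKM in Sirt2-KO.

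Cholesterol synthesis and uptake genes rose as a list, with 2 of 18 past the threshold, both also when adjusted over the list alone (camera adjusted p = 0.00485). For this list adjusted p = 0.857 with an estimated correlation, and the call was lost without Sirt2-KO replicate 7 (adjusted p = 0.0581), with a minimum mean of 20 FPKM (0.0898) and with the replicate number as a block (0.205). The genes that passed were Insig1, which restrains sterol synthesis (13.8 ± 2.72 to 50.9 ± 10.95 FPKM), and the sterol enzyme Nsdhl (5.21 ± 0.0721 to 11.2 ± 0.576 FPKM). Idi1 differed by 0.52 (adjusted p = 0.152). Fatty acid oxidation genes leaned higher as a list (median 0.65, camera adjusted p = 0.00121), with 0 of 29 past the threshold by limma, also adjusted over the list alone, and 8 at an unadjusted p under 0.05. Nuclear-encoded oxidative phosphorylation genes did so by a median of 0.11 (camera adjusted p = 0.0293), with 0 of 76 past the threshold by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05. The lists had adjusted p = 0.857 and adjusted p = 0.868 with an estimated correlation. Without WT replicate 8, the aorta with the lowest Fabp4, neither passed (adjusted p = 0.0867 and 0.432), and the phosphorylation list then leaned lower. That list also missed the threshold without Sirt2-KO replicate 4 (adjusted p = 0.0580) or Sirt2-KO replicate 8 (adjusted p = 0.486), and with quantile normalization (0.676), arrayWeights (0.538) or a minimum mean of 20 FPKM (0.184). Acaa1a (log2 difference 0.47), Eci1 (1.24), Acads (0.90), Sdha (0.58), Ndufs7 (0.39) and Uqcrc1 (0.58) had the smallest p in these lists, from 0.0630 to 0.262 when adjusted over all genes.

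Adventitial fibroblast markers rose together: all 16 tested members were higher, 7 passed over all genes and 14 when adjusted over the list alone. The median log2 difference was 1.47 (camera adjusted p = 1.2e-11, and adjusted p = 0.760 with an estimated correlation). Pi16 rose from 28.4 ± 2.999 to 154 ± 43.5 FPKM, Clec3b from 58.0 ± 18.4 to 337 ± 107 FPKM and the dermatopontin gene Dpt from 48.5 ± 7.65 to 186 ± 59.3 FPKM. Matrix proteases and their inhibitors rose as a list (4 of 25 past the threshold, 8 adjusted over the list alone, camera adjusted p = 6.5e-05). For it adjusted p = 0.760 with an estimated correlation. The stromelysin gene Mmp3 rose from 31.0 ± 5.94 to 123 ± 32.5 FPKM, the procollagen peptidase gene Adamts2 from 23.6 ± 1.71 to 58.3 ± 15.5 FPKM and Mmp23 from 42.2 ± 10.6 to 101 ± 16.3 FPKM.

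Elastic fibre genes also rose as a list, with 3 of 19 past the threshold and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00213). Here adjusted p = 0.857 with an estimated correlation, and the list did not pass without WT replicate 4 (adjusted p = 0.0777). The members that passed were microfibril and fibulin-family genes, Mfap5 (29.4 ± 6.85 to 91.0 ± 12.6 FPKM), Fbln1 (35.2 ± 8.05 to 111 ± 37.8 FPKM) and Efemp1 (13.6 ± 2.46 to 34.1 ± 8.79 FPKM). Eln, the elastin gene, differed by 0.37 (SE 0.452, adjusted p = 0.611) and by -0.18 without WT replicate 4. Of 30 collagens and cross-linking enzymes, the procollagen C-proteinase enhancer Pcolce rose (50.1 ± 6.11 to 174 ± 52.8 FPKM, log2 difference 1.73) and 3 genes rose when adjusted over the list alone. With only its highest row Pcolce differed by 0.56 and did not pass (adjusted p = 0.368). As a list they did not pass (adjusted p = 0.301, direction up, median -0.02), but camera called the list in 2 of 20 alternatives (lowest adjusted p = 0.0356). Col1a1 (1.09, adjusted p = 0.0905) and Col3a1 (0.55, adjusted p = 0.303) missed the threshold.

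Macrophage, complement, MHC class II and mast cell lists were higher in Sirt2-KO. All 20 macrophage markers were higher, with a median log2 difference of 1.23 (camera adjusted p = 1.0e-09, and adjusted p = 0.778 with an estimated correlation). Over all genes 1 passed, against 15 adjusted over the list alone. That gene was Folr2 (5.83 ± 1.52 to 22.6 ± 6.75 FPKM), while C1qa (1.72) and Fcgr3 (1.53) had adjusted p of 0.0502. Complement genes rose as a list, with 17 of 17 higher, 3 past the threshold and 14 adjusted over the list alone (camera adjusted p = 3.4e-09). The list had adjusted p = 0.778 with an estimated correlation. Beside Cfd, C3 rose from 80.1 ± 33.1 to 253 ± 53.4 FPKM and C2 from 7.84 ± 2.02 to 23.8 ± 7.84 FPKM. MHC class II genes rose (4 of 9, 6 adjusted over the list alone, camera adjusted p = 6.5e-05), again with adjusted p = 0.778 with an estimated correlation. Among them H2-Eb1 was at 74.4 ± 19.9 against 22.7 ± 6.34 FPKM, and H2-Aa and H2-Ab1 rose by log2 differences of 1.74 and 1.55. Mast cell proteases Mcpt4 (4.03 ± 0.916 to 17.0 ± 3.02 FPKM) and Cma1 (log2 difference 1.53) rose within their list of 5, where 4 passed adjusted over the list alone. Tpsb2 differed by 1.58 with an adjusted p of 0.0696. The mast cell list had a camera adjusted p = 0.000563, and adjusted p = 0.760 with an estimated correlation.

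Inflammatory cytokines and adhesion molecules leaned higher as a list (camera adjusted p = 0.0122), with 1 of 15 past the threshold, also adjusted over the list alone. Interferon response genes did as well (camera adjusted p = 0.00237), with 0 of 18 past the threshold by limma, also adjusted over the list alone, and 5 at an unadjusted p under 0.05. Each list had adjusted p = 0.857 with an estimated correlation. The eosinophil chemokine gene Ccl11 rose from 5.52 ± 1.17 to 18.5 ± 4.27 FPKM. Ccl7 (1.11), Ccl9 (1.07), Psmb9 (0.73), Psmb8 (0.67) and Rtp4 (0.83) had adjusted p between 0.0696 and 0.112. The cytokine list did not pass without WT replicate 2 or WT replicate 8 (highest adjusted p = 0.166), nor the interferon list without Sirt2-KO replicate 7 (adjusted p = 0.109). With a minimum mean of 20 FPKM neither passed (adjusted p = 0.732 and 0.0820), and the cytokine list was also lost with a minimum of 5 FPKM (0.0780) and with the block (0.0800). Among 11 B and plasma cell genes Ighg2c fell and Ighm rose (26.3 ± 7.04 to 98.3 ± 42.6 FPKM), and the list did not pass (adjusted p = 0.544). Red blood cell genes were higher as a list (camera adjusted p = 0.00197, and adjusted p = 0.778 with an estimated correlation). By limma 0 of 5 passed over all genes, 4 adjusted over the list alone and 4 at an unadjusted p under 0.05, with Hba-a1 at a log2 difference of 1.61, Hba-a2 at 1.49 and Hbb-bs at 1.37.

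Smooth muscle, endothelial, nerve and striated muscle lists were lower. Contractile smooth muscle genes had a median log2 difference of -0.46 over 22 members, 20 of them lower (camera adjusted p = 0.00485, and adjusted p = 0.857 with an estimated correlation). By limma 0 passed over all genes, 1 fell adjusted over the list alone and 6 had an unadjusted p under 0.05. The smallest p were those of the myosin light chain kinase gene Mylk (235 ± 37.2 against 122 ± 23.0 FPKM, adjusted p = 0.0523), Itga8 (-1.10, adjusted p = 0.112) and Synpo2 (-0.84, adjusted p = 0.152). Acta2 (-0.39, adjusted p = 0.553) and Myh11 (-0.48, adjusted p = 0.272) did not pass. Over the alternatives the difference of Acta2 ranged from -0.75 to -0.16. Its WT values were uneven, at 3759 FPKM in replicate 4 against 7435 and 8512 FPKM in replicates 2 and 8. Endothelial markers had a median of -0.25 (camera adjusted p = 0.0441, and adjusted p = 0.868 with an estimated correlation). By limma 0 of 19 passed, also adjusted over the list alone, and 3 had an unadjusted p under 0.05, with Egfl7 at -0.65, Erg at -0.50 and Sox17 at -0.89. The smooth muscle call was lost without WT replicate 2 (adjusted p = 0.0569). The endothelial call was lost without any of 4 aortas, WT replicates 2 and 4 and Sirt2-KO replicates 4 and 7 (highest adjusted p = 0.440). It was also lost with a minimum mean of 5 FPKM (adjusted p = 0.0510) or 20 FPKM (0.0821), median-of-ratios scaling (0.0538), rescaling to an equal sum (0.0572), no trend in the spread (0.0627), arrayWeights (0.168) or the highest row per gene (0.0754).

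Schwann cell and nerve markers fell as a list, with 2 of 17 past the threshold, 3 adjusted over the list alone and a median of -1.25 (camera adjusted p = 0.00328). This list had adjusted p = 0.857 with an estimated correlation. The periaxin gene Prx fell from 11.6 ± 3.17 to 4.21 ± 0.173 FPKM (log2 difference -1.25), but by -0.36 and short of the threshold with only its highest row (adjusted p = 0.372), while Mbp differed by -1.77 (adjusted p = 0.0567). The sympathetic neuron gene Th in the same list was at 109 and 67.2 FPKM in WT replicates 4 and 8 and 63.7 FPKM in Sirt2-KO replicate 4, against 7.87, 2.67 and 5.27 FPKM in the other 3 aortas. Heart muscle markers were lower as a list (1 of 11 past the threshold, 2 adjusted over the list alone, median -1.35, camera adjusted p = 0.0446), with adjusted p = 0.857 with an estimated correlation. They did not pass without WT replicate 4 (adjusted p = 0.739), which held 84.7 FPKM of Myh6 against at most 5.62 FPKM elsewhere, nor without Sirt2-KO replicate 4 (adjusted p = 0.235) or Sirt2-KO replicate 7 (adjusted p = 0.0846). The call was also lost with a pseudocount of 0.1 (adjusted p = 0.0576), a minimum mean of 5 FPKM (0.238), rescaling to an equal sum (0.101), arrayWeights (0.0979) or the highest row per gene (0.0804). In that list the ryanodine receptor gene Ryr2 fell from 6.15 ± 1.20 to 1.66 ± 0.476 FPKM, and Pln (-1.16) and Tnnc1 (-1.40) did not pass. The Tnnc1 difference rested on WT replicate 4, at 21.9 FPKM against 0.317 to 0.916 FPKM in the other aortas. Skeletal muscle markers were lower as a list (camera adjusted p = 0.0441, and adjusted p = 0.760 with an estimated correlation). By limma 0 of 6 passed over all genes, 3 adjusted over the list alone and 3 at an unadjusted p under 0.05, and Pygm (-0.71), Acta1 (-1.16) and Ckm (-1.34) had the smallest p. The call was lost without WT replicate 2, Sirt2-KO replicate 4 or Sirt2-KO replicate 7 (highest adjusted p = 0.132), and with a minimum mean of 5 FPKM (adjusted p = 0.303), rescaling to an equal sum (0.0625) or the block.

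Senescence and secretory genes rose as a list (2 of 19 past the threshold, 6 adjusted over the list alone, median 0.33, camera adjusted p = 0.0107), with adjusted p = 0.760 with an estimated correlation. The members that passed were secreted proteins that fibroblasts also make, Mmp3 and the growth factor binding protein gene Igfbp4 (174 ± 32.5 to 508 ± 163 FPKM), with Igfbp6 at 1.58 (adjusted p = 0.0780). The cell cycle inhibitor gene Cdkn1a differed by -0.28 (SE 0.299, adjusted p = 0.558), and Cdkn2a was not among the tested genes. In the p53 target list (16 tested, adjusted p = 0.330) Perp fell (-0.98) and Phlda3 rose (0.65, adjusted p = 0.0493), both also adjusted over the list alone. The Phlda3 call was lost in 14 of 19 alternatives, among them all 3 other scalings, a minimum mean of 5 FPKM and any mouse left out, and the Perp call in 8 of 19. Shc1, which encodes the redox adaptor p66Shc, differed by -0.28 (SE 0.153, adjusted p = 0.277). Its value sums 3 rows without identifiers, so the transcript of p66Shc was not measured apart. The list of 12 NADPH oxidase genes with Shc1 did not pass (adjusted p = 0.224), with 1 gene lower adjusted over the list alone. Nnt, which makes NADPH in mitochondria, fell from 22.4 ± 4.96 to 5.81 ± 0.955 FPKM and was the only one of 33 antioxidant and redox genes past the threshold, also adjusted over the list alone (adjusted p = 0.361 for the list).

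No list call was made for other sirtuins and NAD metabolism (12 tested, 1 higher adjusted over the list alone, adjusted p = 0.255) or for tubulins and their acetylation enzymes (0 of 13 by limma, also adjusted over the list alone, 0 at an unadjusted p under 0.05, adjusted p = 0.629). TGF-beta signalling (1 of 21 past the threshold, 2 adjusted over the list alone, adjusted p = 0.344), calcification and cartilage (1 of 12, 2 adjusted over the list alone, adjusted p = 0.856) and ribosomal proteins (1 of 44, 0 adjusted over the list alone, adjusted p = 0.153) had none either. In these lists Tgfbi (34.1 ± 10.01 to 121 ± 47.1 FPKM), the cartilage matrix gene Comp (22.2 ± 3.53 to 73.6 ± 19.1 FPKM) and Rplp0 (281 ± 111 to 701 ± 31.7 FPKM) rose. Rplp0 shares sequence with its processed pseudogene copies, so its value is uncertain. Among 13 genes next to Sirt2 on chromosome 7, Gmfg rose (3.14 ± 1.35 to 11.2 ± 2.39 FPKM) and Mrps12 fell (38.6 ± 3.67 to 16.7 ± 5.18 FPKM), both also adjusted over the list alone, with no camera call for the list (adjusted p = 0.842). Fry's mixed test, for change in either direction, gave this list an adjusted p of 0.000154, the smallest of all lists tested. That test called 20 of the 43 lists, so passing it was common. Of the 13 neighbours, 5 had an unadjusted p under 0.05 by limma, as did 2132 of all 8605 tested genes. Vasoactive receptors, glycolysis, mitochondrial dynamics, circadian clock, immediate early, heat shock, unfolded protein response, cell cycle, lymphatic, neutrophil and nuclear-retained RNA lists were not called either, with adjusted p from 0.164 for neutrophils to 0.959 for the clock. In them 0 genes passed by limma over all genes, with 7 vasoactive and 7 glycolysis genes at an unadjusted p under 0.05. Adjusted over the list alone, 3 vasoactive genes and 1 nuclear-retained RNA fell, 3 glycolysis genes rose and 3 fell, 1 cell cycle gene rose and 1 fell, and 1 lymphatic gene rose. The lymphatic list (median -0.49, direction up) and the clock list (median 0.03, direction down) differed in sign between median and test. Only 3 of 28 cell cycle genes, 3 of 12 neutrophil genes, 4 of 11 nuclear-retained RNAs and 5 of 7 lymphatic genes were tested. Those lists therefore say little.

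**Figure D2:**
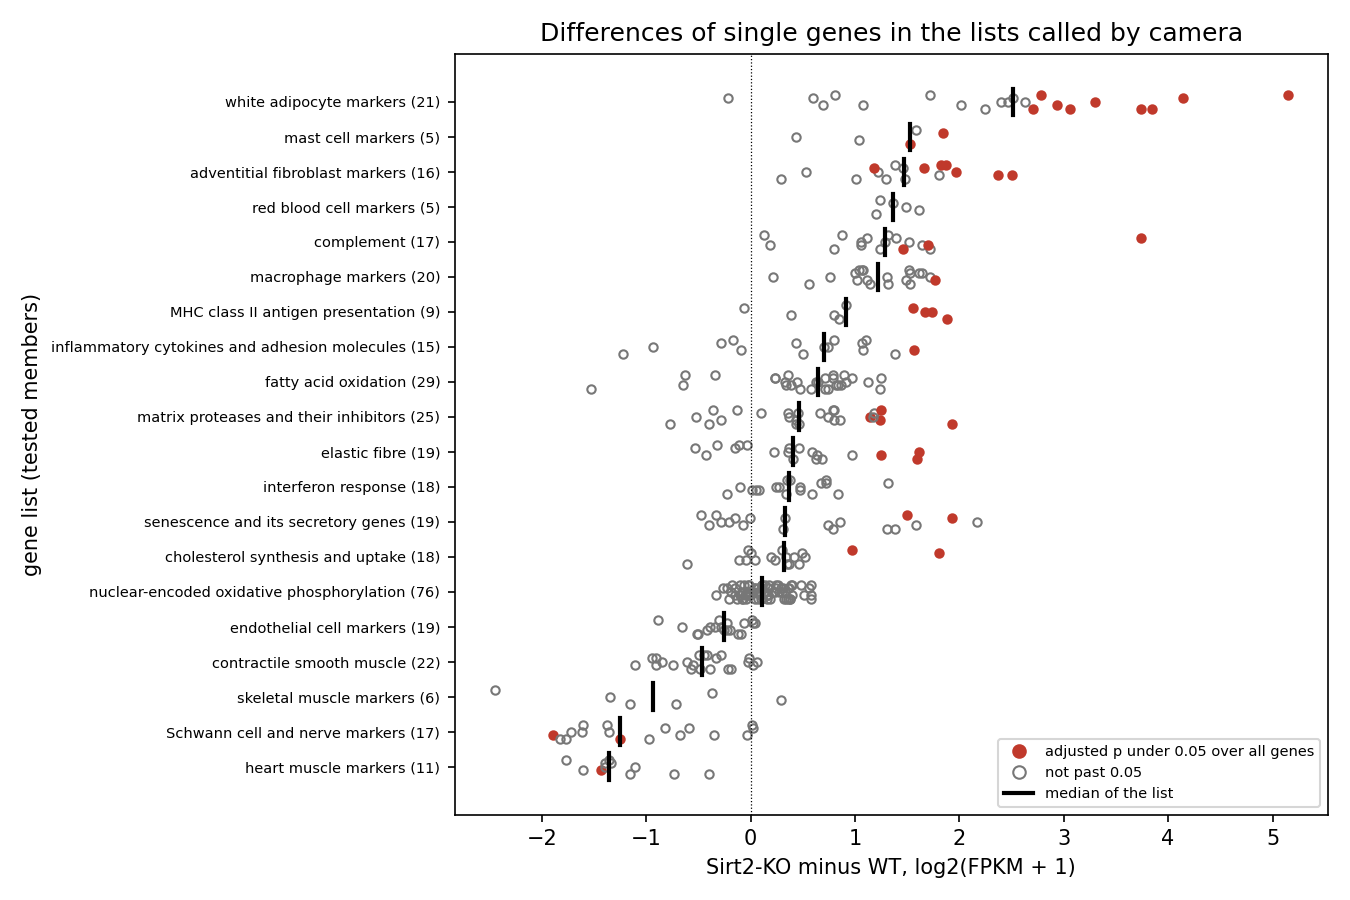
Sirt2-KO minus WT difference on the log2(FPKM + 1) scale (x) of each tested member of the 20 gene lists that camera called with the preset correlation (y, number of tested members in parentheses), with filled points for genes past an adjusted p of 0.05 over all genes and a bar at each list's median. The white adipocyte list has the highest median, 2.51, and the heart muscle list the lowest, -1.35.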

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

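The fits with a minimum mean of 20 FPKM and with only the highest row of each gene were chosen after seeing the data. The count of 250 changed genes stayed within 1.5 times under both other pseudocounts, the filters at any value above 0 and at a mean of 5 FPKM, the 3 other scalings and both other spread models, from 190 genes with samples rescaled to an equal sum to 254 with quantile normalization. It was 1114 with arrayWeights (706 higher and 408 lower) and 151 with only the highest row of each gene, and the cause was not tested. It was 141 with a minimum mean of 20 FPKM, where 3337 genes were tested and 131 of the 250 remained testable. Leaving out 1 mouse gave 28 to 342 genes. With the replicate number as a replicate block, only the mice numbered 4 and 8 inform the difference and 1 residual degree of freedom remains, and the count was 3. The number was not taken as a pairing, because nothing in the labels says that it pairs mice. Deviations of same-numbered mice from their group means correlated at -0.0493 for number 4 and -0.452 for number 8. So few pairs, with deviations from means of 3 samples, cannot exclude a pairing. Under the block the Sirt2 level differed by -3.63 with an adjusted p of 0.0792. In the other 17 fits it kept its direction and its call, from -4.16 to -3.08, and from -3.51 to -3.08 with a mouse left out. Of 43 lists, 20 were called (5 lower), 17 rescaled to an equal sum (2 lower), 0 with an estimated correlation and 0 by fry. With a mouse left out 16 to 20 were called. A minimum mean of 5 FPKM left 42 lists to test, with 16 called (2 lower). With a minimum of 20 FPKM 35 lists could be tested and 13 were called. In the other fits 18 to 20 lists were called. The robust fit has no counterpart in camera and was not run for lists. With any mouse left out, 10 of the 20 list calls held. The collagen, heat shock, neutrophil, ribosomal protein and vasoactive lists, not called in the main fit, were called in 2 alternatives each. The B and plasma cell list was called in 1. Among 96 named genes, Cdkn1a and Eln changed sign, both without WT replicate 4 and neither past the threshold. Over the mice left out, Cdkn1a ranged from -0.50 to 0.062 and Eln from -0.18 to 0.65. The oxidative phosphorylation list turned lower without WT replicate 8 (adjusted p = 0.432), with adjusted p from 0.000170 to 0.486 over the mice left out. Of the 58 named genes that passed, 57 were not called under the block, 17 with only the highest row, 43 without Sirt2-KO replicate 7 and 43 without Sirt2-KO replicate 8. Calls of Phlda3 (14 of 19), Tgfbi (12 of 19), Mrps12 (11 of 19), C2 (11 of 18), Igfbp4 and Rplp0 (10 of 19 each) were lost in most alternatives. Depth is unknown, and the missing low-variance rows limit statements about genes that did not change.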

Other observations

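The tests of fat cell share, smooth muscle share (with and without the 6 genes of the neuron split) and neighbouring genes (with and without the genes that prompted it), the per-gene criterion for the length trend, and the genes named here outside the rule were chosen only after the result was seen. Some sympathetic neuron genes, picked from the 97 genes called for another split of the aortas, divided them across genotype. Neuron genes were not tested as a set on that split. Slc6a2, the noradrenaline transporter, was at 32.1, 28.8 and 33.2 FPKM in WT replicates 4 and 8 and Sirt2-KO replicate 4 and at 2.85, 1.80 and 2.40 FPKM in WT replicate 2 and Sirt2-KO replicates 7 and 8. Dbh, which makes noradrenaline, was at 104, 74.0 and 71.5 FPKM against 5.83, 2.85 and 5.76 FPKM. Rplp0 was at 199, 235 and 407 FPKM in WT and 729, 667 and 708 FPKM in Sirt2-KO, while the pseudogene model Gm8730 was at 274, 310 and 152 FPKM in WT and 4.27, 3.36 and 4.49 FPKM in Sirt2-KO. By limma Gm8730 differed by -5.56 (adjusted p = 0.000321) and Gm9625 by -3.75 (adjusted p = 0.00272), opposite to Rplp0. The sum of Rplp0, Gm8730 and Gm9625 differed by 0.29 on the log2 scale, against 1.39 for Rplp0 alone. The split of values between these copies thus differed along the 2 groups, and its cause was not tested.

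Of the 10 splits of the 6 aortas into 3 and 3, the real split, with 250 genes, was the 1 split with as many, and the highest other gave 97 genes. A share under 0.05 is out of reach with 10 splits, and that other split is the one of the neuron genes. Longer transcripts leaned lower in Sirt2-KO, and taking off that trend left 77.8% of 243 called genes past the threshold, just under the 80% set beforehand as speaking against it. By a criterion added afterwards, the trend exceeded 50% of the difference in 0 of the called genes (largest trend 0.49, median absolute difference 1.58). Called genes were picked for large differences, so that outcome was nearly fixed in advance and a part played by length stays undecided. Alleles of the founder strain carried beside the knocked-out gene stay open: 5.10% of 157 tested genes within 10 Mb of Sirt2 in GRCm38 were called, against 2.78% on other chromosomes (one-sided Fisher's exact test, p = 0.0762). Fry's mixed test passed for the 13 genes next to Sirt2 (adjusted p = 0.000154). It passed for 20 of 43 lists in all, so it does not tell carried alleles from other causes.

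The rise of fat cell genes may come from several sources, a larger share of fat cells among them. The mean of Fasn, Scd1, Acaca, Acly and Thrsp minus that of Adipoq, Plin1, Cidec, Lipe and Fabp4 was 1.85 higher in Sirt2-KO on the log2 scale. The former hold the largest rises, so this gap does not speak against a larger share of fat cells. A lower share of smooth muscle alone would raise every other cell type, but the Schwann cell and nerve list had a median of -1.25 (adjusted p = 0.857 with an estimated correlation), with 6 of its genes in the neuron split. Without these 6 the median of the other 11 was -0.82, 9 of them lower, and their mean level was lower in each Sirt2-KO aorta than in each WT aorta, while the mean of the fibroblast list was higher in each. Another stretch of aorta or its fat is a candidate explanation, and 14 tested Hox genes mark body position. Paralog groups 8 to 13 were counted as posterior beforehand. Hoxc8, in the lowest of these groups, was higher in Sirt2-KO (3.62, 4.39 and 2.99 FPKM in WT against 7.15, 7.27 and 8.38 FPKM, limma adjusted p = 0.0257 over the Hox genes and 0.0551 over all genes). The anterior Hoxb2 was lower (log2 difference -0.79, adjusted p = 0.0332 over the Hox genes and 0.0782 over all genes). The other 3 counted as posterior, Hoxb8 (0.25), Hoxc10 (0.39) and Hoxd9 (-0.09), overlapped between the groups (adjusted p of at least 0.483 over the Hox genes). An effect of Sirt2 loss on lipogenesis stays open as well and was not separated from position or fat cell share.

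Several genes differed without an evident link to a cell type. Nnt was lower, with uneven WT values (21.3, 18.0 and 27.8 FPKM). Its limma call was lost without Sirt2-KO replicate 7 or Sirt2-KO replicate 8 (highest adjusted p = 0.0602). Ide (10.5 ± 0.446 to 17.8 ± 1.04 FPKM, adjusted p = 0.0282), Entpd4 (adjusted p = 0.0282) and the neighbours Plac9a, Plac9b, Tmem254a, Tmem254b and Gm9780 on chromosome 14 (GRCm38) were higher. Nnt carries a known deletion in the C57BL/6J substrain, so stretches of chromosome that differ between the 2 groups of mice are a candidate source. In a test of that, 39 called genes lay within 200 kb of another called gene of the same direction, against a median of 20 in 100000 random draws (permutation p = 0.003), but the 5 chromosome 14 neighbours that prompted the test, near-identical copies that can share reads among them, count in the 39, and without the prompting genes it was 34 against 19 (p = 0.0117). Families expressed together, such as H2-Aa with H2-Ab1 and Cma1 with Mcpt4, count in both, as does the knocked-out Sirt2 with its neighbour Mrps12. The test therefore does not separate shared regulation from shared alleles, and the labels do not give the substrain of either group.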
